A study of Arabidopsis thaliana with 4 samples.

How the data were processed

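Small RNA was sequenced from 4 fractions of Arabidopsis inflorescences: the input and the HA co-IP of plants with HA-AGO2, and the input and the HA co-IP of plants with HA-AGO7. Each sample was assigned to its group by its title in the labels, 1 library per group. Per the labels' protocols, RNA was taken from the input directly and from the beads after proteinase K, and the libraries were sequenced on an Illumina 1G instrument. The authors deposited ELAND output, per the series' design text, with 1 read of 36 bases per line, a match code and numbers of genomic matches, and no counts or normalised values. From the reads themselves, the 3' adaptor CTGTAGGCACCATCAATTCGTA was still in place, and the facility's alignment had matched 0.0558%, 0.102%, 0.0801% and 0.729% of the reads of the AGO2 input, AGO2 co-IP, AGO7 input and AGO7 co-IP. The ELAND version and genome build are not given in the sources used here, so the deposited match codes were not used further.

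Reads were trimmed at the first exact match to the first 8 nt of the adaptor, and inserts of 18 to 28 nt without an N were kept: 903961, 2789746, 395575 and 1500746 in the same order. Reads without the adaptor made up 26.1%, 52.8%, 17.3% and 36.8%, inserts too short made up 54.4%, 7.93%, 75.1% and 15.9%, and reads that began with the adaptor 0.145%, 1.65%, 0.175% and 21.5%. Inserts were matched without mismatches to both strands of the TAIR10.1 assembly with its RefSeq annotation, keeping all hits, with a search written in Python 3.11.15 (NumPy 2.4.6, SciPy 1.17.1, numba 0.67.0), and 77.7%, 47.9%, 70.9% and 53.9% had a match. Figures were drawn with matplotlib 3.10.9. A perfect match removes reads with a sequencing error or a strain variant, and PCR copies cannot be told from separate molecules.

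Each matched sequence was put in the first class that fitted, in the order miRNA, rRNA, tRNA, snRNA or snoRNA, TAS locus, other miRNA precursor, organelle, and remaining genome, where multiple hits were shared equally. rRNA included the sense strand for 4000 nt downstream of the 5.8S genes and 211 copies of the 5S gene found by sequence, which the annotation lacked. A read counted for a miRNA strand when both of its ends lay within 2 nt of an annotated mature strand. The 428 annotated strands were divided into 335 guide and 93 star strands and grouped into 212 families. Strands of genes annotated on a single arm of the precursor were all taken as guides. For genes annotated on both arms the guide was set by the sequence in the annotation's notes or, without one, by the reads of the inputs. TAS reads were reads of 20 to 22 nt on either strand of TAS1A, TAS1B, TAS1C, TAS2, TAS3A, TAS3B, TAS3C and TAS4. Transposable elements were not annotated in the reference used here, so the list of 24-nt sequences from transposable elements or outside genes became one of sequences outside genes or in pseudogenes.

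Values computed here are reads scaled to the genome-matched reads of 18 to 28 nt of the library (RPM). Log2 ratios of co-IP over input used a pseudocount of 0.5 read, and folds used none. A family (at least 10 reads in the pair of libraries) or a sequence of 20 to 24 nt (at least 50 reads) was called when its fold was at least 2 and the exact conditional binomial 95% interval of the ratio excluded 1. Shares have Wilson 95% intervals, a difference of log2 ratios has a normal interval on log counts, and a count of 0 was set to 3 reads to give a bound. Such calls compare libraries, not conditions, and fold intervals of fractional counts used rounded counts. Lists fixed before the data were examined were conserved families, less conserved families, the tasiRNA triggers miR173, miR390 and miR828, star strands, tasiRNAs, 24-nt sequences, background RNA, families by 5' base and the reads of the AGO2 and AGO7 genes. A list's median was set beside those of 10000 random lists of the same size matched on abundance, as a description of these libraries.

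Features were named by a rule fixed before the data were examined. For each co-IP it took miR390, miR173, miR828 and each TAS family, the 8 highest and 8 lowest families with at least 100 reads, the 5 most abundant families of the co-IP, and the 5 highest sequences with at least 200 reads outside miRNA and TAS loci. Between the proteins it took the 5 families with the largest difference each way. Other features are named as chosen after their values were seen, and miR172 and miR8175 are also named for AGO7 and by 5' base.

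The calling rule was tested on simulated data. For the AGO2 pair, 821 sequences were drawn with 200 of them changed, and all 4-fold and 8-fold changes were called, as were 6 of 621 unchanged sequences (0.966%). For the AGO7 pair, 54 sequences were drawn with 27 of them changed, all of which were called, and 0 of 27 unchanged ones were. The counts were drawn with counting error alone, so these shares leave out differences between libraries and are no error rate for the real calls. Between the 2 inputs the same rule called 6 families higher and 5 lower of 46. The trimming recovered 996 of 996 simulated insert lengths, and the number of genomic matches equalled that of a plain text search for 200 of 200 matched and 200 of 200 unmatched inserts. The 16 alternatives fixed before the data were examined covered the totals, the adaptor match, exact mature sequences, unique matches, minimum reads, the fold, the range between the inputs, the other construct's input, the pseudocount and the reads behind the 5' A share, and 2 scalings were added later, as were counts without reads shared between families and families grouped by the 5' base of most of their reads. The trimmed mean of M-values was computed with code written for this work, since the deposited units are reads and not a table of counts. Inserts with no genome match were not analysed here beyond their number.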

Results

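The series sequenced small RNAs of Arabidopsis thaliana inflorescences (flower stages 1 to 12) that were bound to ARGONAUTE2 (AGO2) or ARGONAUTE7 (AGO7), the proteins that carry small RNAs to their target transcripts. Each protein carried an HA epitope tag and was expressed from its own promoter, AGO2 in wild-type Col-0 plants and AGO7 in zip-1, a mutant of the AGO7 gene. Lysates were divided into an input fraction and an HA co-immunoprecipitation (co-IP) fraction, which gave 4 libraries in 4 groups. With 1 library per group there was no replicate check, so no p-value is given, and all intervals are 95% intervals that cover counting error only, since amplified reads carried no molecular identifiers. The AGO2 input held 4735194 reads, the AGO2 co-IP 7644133, the AGO7 input 5403495 and the AGO7 co-IP 5883923. Inserts of 18 to 28 nt with a perfect genome match numbered 702357 in the AGO2 input, 1335103 in the AGO2 co-IP, 280355 in the AGO7 input and 808639 in the AGO7 co-IP. Reads were scaled to these totals (RPM), and 3 reads, the limit that a count of 0 allows, stood for 4.27, 2.25, 10.7 and 3.71 RPM in the same order.

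The AGO2 co-IP was rich in miRNA reads, most of them of miR159, while the AGO7 co-IP consisted mainly of rRNA fragments. Reads of miRNA strands made up 5.68% (5.62 to 5.73, Wilson interval) of the AGO2 input and 31.2% (31.1 to 31.2) of the AGO2 co-IP, a 5.49-fold rise (5.43 to 5.55). In the AGO7 pair the miRNA share was 4.56% in the input and 2.01% in the co-IP, 2.26-fold lower. Among reads outside structural and organelle RNA the direction turned, from 10.8% in the AGO7 input to 29.8% in the co-IP (2.77-fold higher, 2.71 to 2.84), and with AGO2 the share went from 14.5% to 45.4% (3.13-fold, 3.10 to 3.16). The miR159 family alone gave 23834 of the 39866 miRNA reads of the AGO2 input and 358020 of the 415924 of its co-IP. The rises with AGO2 thus rest mostly on miR159, and the median of the 64 measured families lay below input (log2 -1.01). rRNA rose in both co-IPs, from 8.44% to 29.0% with AGO2 and from 22.2% to 88.2% (88.1 to 88.3) with AGO7. tRNA fragments, the most abundant of these RNAs in both inputs at 49.8% and 30.3%, fell to 1.22% and 2.34%, which was 40.9-fold and 13.0-fold lower. Reads of snRNAs and snoRNAs went from 0.764% to 0.445% with AGO2 and from 1.85% to 1.09% with AGO7, and chloroplast and mitochondrial reads from 1.93% to 0.761% and from 3.37% to 1.64%. Together these background RNAs made up 60.9% of the AGO2 input, 31.4% of the AGO2 co-IP, 57.7% of the AGO7 input and 93.3% of the AGO7 co-IP, so every AGO7 ratio below is given against a total filled by rRNA.

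**Figure D1:**
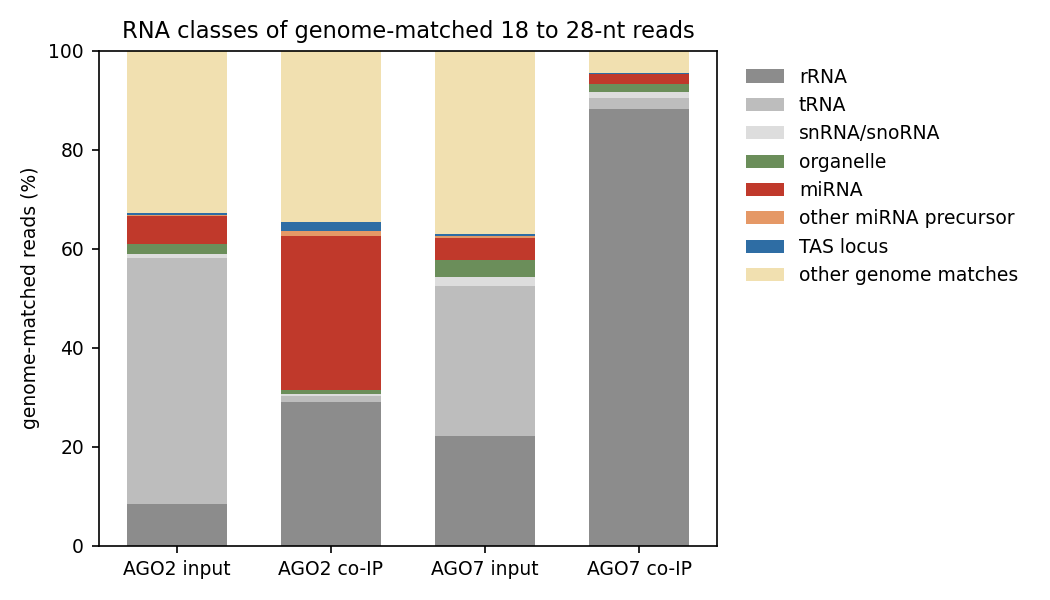
Share of genome-matched reads of 18 to 28 nt (vertical axis, percent) in each RNA class for the 4 libraries, as stacked bars. miRNA reads made up 31.2% of the AGO2 co-IP, and rRNA reads 88.2% of the AGO7 co-IP.

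The comparison of the AGO2 co-IP with its input asks which small RNAs AGO2 holds in flowers. Most measured families whose annotated guide strand begins with A rose, and most families that begin with U fell: 14 of 17 measured A families were higher and 1 was lower, against 3 higher and 27 lower of 42 U families. The minimum of 10 reads counted both libraries, so families with few input reads were measured only if the co-IP held many. Such families could hardly come out lower, as with miR837, miR840, miR852 and miR866, which had 0, 1, 0 and 0 input reads. Among A families with at least 10 input reads, miR172 (277), miR390 (71) and miR408 (214) rose and miR869 (12) fell. miR5595 and miR5995 consist of the same 20 reads, and counted once they leave 13 of 16 A families higher. All counts by base are for the main totals. Without structural and organelle RNA in the totals, the higher families of all bases together fell from 18 to 12. By the base of most reads in place of the annotation, 13 of 18 A families were higher and none lower, against 3 higher and 28 lower of 40 U families. That base came from the reads of both libraries, so the co-IP helped to set the grouping and it is no independent check. It moved miR841 (281 of 286 reads with A) and miR160 (821 of 1393) from U to A. miR408, which targets transcripts of copper proteins such as plantacyanin and laccases, rose 24.8-fold (21.7 to 28.5), from 214 to 10093 reads. miR390, the trigger of trans-acting siRNA (tasiRNA) production from TAS3 transcripts, rose 4.08-fold (3.18 to 5.29), from 71 to 550 reads, although its log2 ratio of 2.02 lay within the central 95% of the family ratios between the inputs, which reached 2.06. miR172, which regulates AP2-like floral transcription factors, rose 2.80-fold (2.46 to 3.19), a call that was lost with totals without structural and organelle RNA (log2 0.67), of 20 to 24-nt reads (0.76) or of all trimmed inserts (0.78), and its main log2 ratio of 1.48 also lay within the range between the inputs. miR159, which regulates MYB transcription factors and begins with U, rose 7.90-fold (7.80 to 8.01) and took 92.1% of the family reads of the co-IP, against 63.1% of those of the input.

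Of 64 families with at least 10 reads in the AGO2 pair, 18 were higher in the co-IP, 31 were lower and 15 were neither, by a rule of at least 2-fold with a counting interval that excludes 1 (17 higher of 63 with miR5595 and miR5995 counted once). The median family lay at a log2 ratio of -1.01, and relative to it miR408 stood at 5.64, miR390 at 3.03 and miR172 at 2.49. The split moved with the scaling: 26 families were higher and 22 lower with trimmed mean of M-values factors, 24 and 26 with the median family set to a ratio of 1, and 12 and 34 with totals of 20 to 24-nt reads, of all trimmed inserts or without structural and organelle RNA. The 4 measured families that begin with C held 3 that fell and none that rose, and the 1 that begins with G, miR8175, rose 7.98-fold (3.53 to 22.3), although 72 of its 97 reads began with U and it lay below the AGO7 input (log2 -1.45). By the base of most reads, 5 families began with C, of which 3 fell and 1, miR840, rose.

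Beyond these, the highest ratios among the 25 families with at least 100 reads belonged to families that were nearly absent from the input. miR5643 went from 6 to 515 reads (45.2-fold, 20.6 to 124) and miR5027 from 5 to 406 reads (42.7-fold, 18.2 to 132). miR852 went from 0 to 125 reads, at least 21.9-fold higher, but its exact mature sequence had no reads in either library, so all of these reads differed from it by up to 2 nt at their ends. miR841 went from 1 to 285 reads (150-fold, 26.7 to 5942). Of those 285 reads, 282 fell at the annotated miR841b-3p strand, which begins with C where the other guides of the family begin with U, and the exact mature sequences had 1 co-IP read and none in the input, too few to measure. Of the 286 reads of the pair 281 began with A, and 276 reads of the co-IP also count for the miR841 star strand, whose annotated sequence is shifted by 2 nt. At the other end, miR845 was 30.8-fold lower (18.6 to 54.6), miR867 24.3-fold (13.8 to 46.5) and miR824, which targets the MADS-box gene AGL16, 21.8-fold (16.7 to 29.1). miR164, which targets NAC transcription factors of organ boundaries, was 20.5-fold lower (13.1 to 33.8) and miR396, which targets growth-regulating factors, 20.4-fold (14.9 to 28.6). miR163 was 18.1-fold lower (13.5 to 24.6), miR776 15.5-fold (13.2 to 18.3) and miR780 12.1-fold (7.85 to 19.5). The other abundant families of the co-IP passed the rule in neither direction: miR319 at 1.84-fold (1.75 to 1.94), miR168, which targets AGO1, at 1.21-fold (1.15 to 1.28) and miR161 at 1.07-fold (1.01 to 1.15), the last 2 of which lay below 1 with totals without structural and organelle RNA (log2 -0.53 and -0.71). All 3 were higher relative to the median family (1.90, 1.29 and 1.12) and by the trimmed mean of M-values (2.22, 1.61 and 1.44). The miR161 family sums 2 guides that went apart, miR161.1 at 1.34-fold (1.24 to 1.44) and miR161.2 4.45-fold lower (3.63 to 5.48). Its exact mature sequences went from 473 to 192 reads. miR173, the trigger of TAS1 and TAS2 tasiRNAs, had 3 input reads and no co-IP reads, and miR828 had no reads, so neither could be measured.

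Some star strands, the partners of the guide strands in the miRNA duplex, rose strongly in the AGO2 co-IP. Of 23 measured star families 12 were higher and 9 lower, and their median log2 ratio of 1.37 stood at the 96.7th percentile of 10000 random lists of the same size matched on abundance. One of the 12 was the miR841 star strand, whose 276 reads were also counted for its guide family, and without it 11 of 22 were higher, with a median of 0.65 at the 87.7th percentile. Star families with few input reads were measured only if the co-IP held many, so they could hardly come out lower. Those of miR394, miR472 and miR408 had 1, 3 and 4 input reads. Among star families with at least 10 input reads, those of miR393 (85), miR396 (104), miR398 (13) and miR403 (12) rose. Those of miR156/miR157, miR158, miR159, miR168, miR169, miR172, miR390 and miR824 fell, and that of miR170/miR171 did neither. The miR396 star strand rose 102-fold (84.1 to 125), from 104 to 20166 reads, where its guide fell 20.4-fold. Of these co-IP reads 20137 fell within 2 nt of the annotated miR396b-3p strand, which begins with G. The star strand of miR393, whose guide targets auxin receptor transcripts, rose 33.3-fold (26.8 to 41.7), from 85 to 5374 reads. Of these co-IP reads 5352 fell at the annotated miR393b-3p strand, which begins with A. The miR390 star strand, which begins with C, went the other way, from 182 to 3 reads, 115-fold lower (38.8 to 564). These 3 star families were singled out after their values were seen. Conserved families had 4 of 20 measured members higher and 10 lower (median log2 -1.59, percentile 38.6), and less conserved families 6 of 31 higher and 19 lower (median -2.31, percentile 6.16).

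Small RNAs from the TAS1 and TAS2 loci, the sources of tasiRNAs, rose with AGO2. All TAS loci together went from 2669 to 25442 reads of 20 to 22 nt, 5.02-fold higher (4.82 to 5.22). TAS1 rose 10.7-fold (9.81 to 11.7) and TAS2 4.01-fold (3.81 to 4.22), while TAS3, whose tasiRNAs target auxin response factors, was at 1.70-fold (1.53 to 1.90) and passed in neither direction as a whole. Of its loci TAS3B was higher (2.22-fold, 1.86 to 2.65), as was TAS3C (5.45-fold, 2.93 to 11.2, from 11 to 114 reads), and TAS3A was neither (1.25-fold, 1.08 to 1.45). TAS3 as a whole was higher relative to the median family (log2 1.78) and by the trimmed mean of M-values (2.10), and stood at -0.043 without structural and organelle RNA. Among the other loci TAS1B (chromosome 1, 18549204 to 18550042) rose 23.7-fold (19.9 to 28.5), and TAS4 had 5 co-IP reads and none in the input. Of single tasiRNA sequences of 20 to 24 nt with at least 50 reads, 46 of 52 were higher and 6 lower (median log2 4.33, percentile 22.1 among sequences of like abundance). The share of TAS reads that begin with A went from 15.0% (13.7 to 16.4) to 76.6% (76.1 to 77.1), and for TAS3 from 9.93% (7.48 to 13.1) to 95.4% (94.2 to 96.4).

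**Figure D2:**
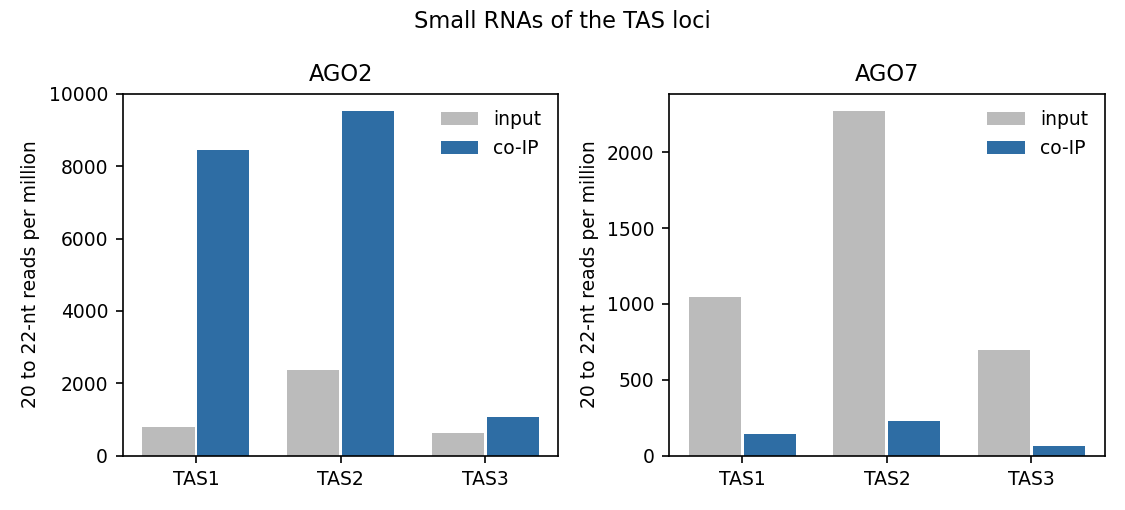
RPM of reads of 20 to 22 nt (vertical axis, separate scales) at the TAS1, TAS2 and TAS3 loci, with grey bars for input and blue bars for co-IP. TAS1 stood 10.7-fold and TAS2 4.01-fold above input with AGO2, and all 3 stood below input with AGO7 by these totals.

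Reads with a 5' A were more frequent in the AGO2 co-IP than in its input. Among all 21-nt reads the share with a 5' A went from 12.5% (12.3 to 12.7) in the input to 40.1% (40.0 to 40.2) in the co-IP. Without structural, organelle and miRNA reads it went from 30.1% (29.5 to 30.8) to 95.6% (95.5 to 95.7) at 21 nt, from 26.5% to 98.4% at 22 nt and from 55.2% to 89.6% at 24 nt. Reads of 21 nt made up 20.1% of the reads outside structural and organelle RNA in the input and 72.2% in the co-IP, and 24-nt reads 42.7% and 4.74%. Outside genes or in pseudogenes, 24-nt reads were 4.95-fold lower in the co-IP and 21-nt reads 6.90-fold higher. Of 44 measured 24-nt sequences from such places 10 were higher and 28 lower, and their median log2 ratio of -2.87 lay below all random lists of like abundance.

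**Figure D3:**
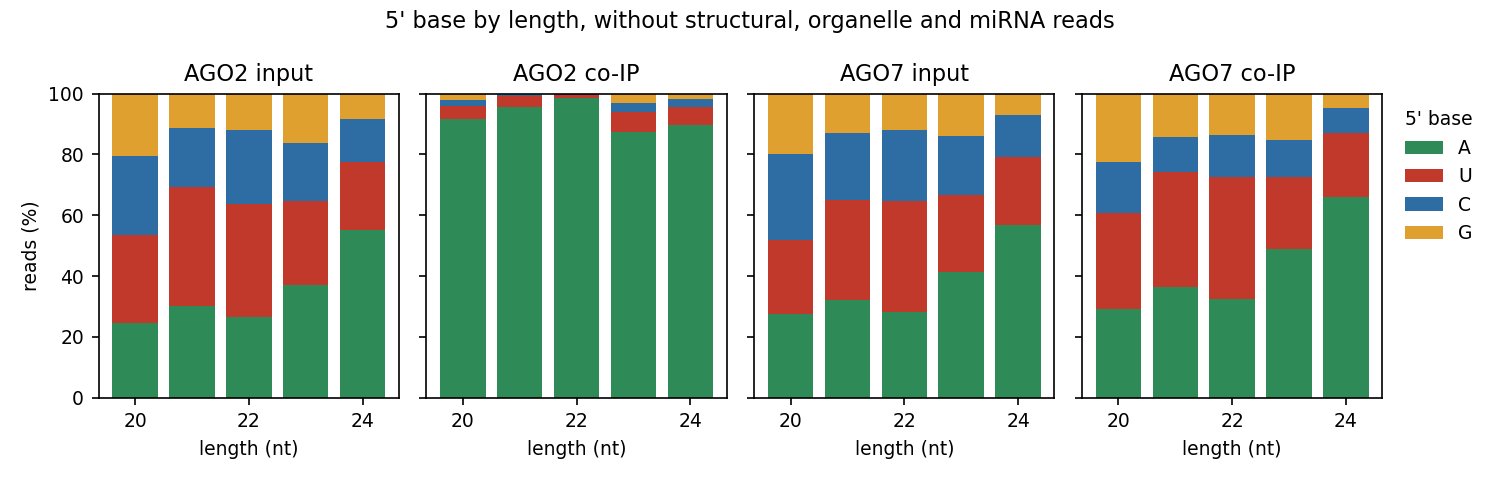
Share of reads by 5' base (vertical axis, percent) for inserts of 20 to 24 nt (horizontal axis) in the 4 libraries, without structural, organelle and miRNA reads. At 21 nt the share that begins with A was 30.1% in the AGO2 input, 95.6% in the AGO2 co-IP, 32.3% in the AGO7 input and 36.6% in the AGO7 co-IP.

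Of 821 distinct sequences of 20 to 24 nt with at least 50 reads in the AGO2 pair, 699 were higher and 105 lower, and 679 (97.1%, 95.6 to 98.1) of the higher ones began with A, against 36 (34.3%, 25.9 to 43.8) of the lower ones and 723 (88.1%, 85.7 to 90.1) of all 821. That minimum counted both libraries, so sequences rare in the input were measured only if the co-IP held many. The split and the shares by base thus depend in part on the minimum. Without one, 4962 of 309806 sequences were higher and 4066 lower. The 5 with the highest ratios outside miRNA and TAS loci had no input reads. AATCTCAGTGGATCGTGGCAGC had 3487 co-IP reads, at least 611-fold higher, and AATCTCAGTGGATCGTGGCAG 474, at least 83.1-fold higher. Both lie antisense to the 45S rRNA repeat, at 9475 to 9496 and 9476 to 9496 on chromosome 2 and at other copies. AAAAATTGTTGCCGTTGGGGAA (408 reads, at least 71.5-fold) matched chromosome 3 at 1965694 to 1965715, outside genes, and at 1968457 to 1968478 in an exon of AT3G06435, which encodes an uncharacterised protein. ATGTTATGCGTCCTATCTTCCT (321 reads, at least 56.3-fold) lay nearby at 1966484 to 1966505, antisense in the long noncoding gene AT3G01835. AGATGCCTTTGTAATTACGGA (327 reads, at least 57.3-fold) matched exons of RPF3 (AT1G62930, chromosome 1, 23307425 to 23307445) and AT1G63130 (23413748 to 23413768), both annotated as tetratricopeptide repeat-like proteins.

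The comparison of the AGO7 co-IP with its input asks which small RNAs AGO7 holds. miR390 (AAGCTCAGGAGGGATAGCGCC, from MIR390a on chromosome 2 at 16061971 to 16061991 and MIR390b on chromosome 5 at 23636961 to 23636981) stood first of 37 measured families and was the only family to rise by the main totals. It rose 4.63-fold (3.31 to 6.65), from 37 to 494 reads, and its share of all family reads went from 0.332% to 3.09%. Its star strand fell 14.9-fold, from 299 to 58 reads. Counting only the exact mature sequence, miR390 rose 13.0-fold (7.35 to 25.3). Of the other families, 28 were lower and 8 neither, and the median family lay at a log2 ratio of -2.59, so that miR390 stood 4.79 above it on the log2 scale, or 27.6-fold.

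The fall of the other AGO7 families depended on the rRNA in the total. Without structural and organelle RNA in the totals the median family moved up by 2.65 on the log2 scale, and 8 families were higher and 7 lower. Trimmed mean of M-values factors gave 7 higher and 13 lower, and the median family set to a ratio of 1 gave 8 and 8. miR408 (log2 0.13), miR161 (0.10), miR8175 (-0.64), miR159 (-0.64) and miR319 (-0.76) passed in neither direction by the main totals, and were all higher without structural and organelle RNA, at log2 ratios of 2.78, 2.75, 2.01, 2.01 and 1.89. The 2 guides of the miR161 family went apart by the main totals, miR161.1 at 0.57 and miR161.2 at -2.60. miR159 was the most abundant family of the co-IP with 66.8% of its family reads, ahead of miR161 (8.03%), miR167 (6.21%), miR168 (3.87%) and miR319 (3.67%).

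miR824 and miR396 were the lowest of the 17 families with at least 100 reads in the AGO7 pair. miR824 was 62.5-fold lower (35.2 to 123) in the co-IP and miR396 19.2-fold (14.0 to 26.8), and both stayed past the rule without structural and organelle RNA. miR845 was 11.5-fold lower (7.57 to 18.1), miR394, which targets an F-box gene, 9.33-fold (6.30 to 14.1) and miR780 6.83-fold (4.40 to 10.8), none of which passed without that RNA. miR160 was 6.06-fold lower (4.42 to 8.38), miR776 4.42-fold (3.83 to 5.11), miR168 3.84-fold (3.46 to 4.27), miR172 3.55-fold (2.77 to 4.54), miR167, which targets auxin response factors, 3.38-fold (3.10 to 3.68), and miR165/miR166, which regulates HD-ZIP III leaf polarity genes, 3.34-fold (2.80 to 3.99), but without that RNA these 6 lay above input, at log2 ratios of 0.06, 0.51, 0.71, 0.82, 0.89 and 0.91. miR173 had 1 input read and no co-IP reads and miR828 none.

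By 5' base, the 4 measured A families held 1 that rose, miR390, and 1 that fell, miR172, while 25 of 29 U families and 2 of 3 C families fell and the only G family, miR8175, did neither, with 98 of its 149 reads beginning with U. Conserved families had 1 of 17 higher and 12 lower (median log2 -1.83, percentile 95.2 among random lists). Less conserved families had 15 of 17 lower and none higher (median -3.24, percentile 9.10). Of 13 measured star families 12 were lower and none higher (median -3.88, percentile 5.81).

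TAS loci did not rise with AGO7. Together they went from 1126 to 355 reads, 9.14-fold lower (8.11 to 10.3), with TAS1 7.37-fold, TAS2 9.87-fold and TAS3 10.4-fold lower, and the log2 ratio of -3.19 became -0.54, no longer past the rule, without structural and organelle RNA. All 5 measured tasiRNA sequences were lower (median log2 -2.94, percentile 51.8), as were both measured 24-nt sequences outside genes or in pseudogenes (median -3.78, percentile 13.1), and TAS4 had no reads. Reads of 24 nt outside genes or in pseudogenes were 10.9-fold lower and those of 21 nt 7.43-fold lower, again by totals that rRNA filled (log2 -0.79 and -0.24 without structural and organelle RNA). Of 54 distinct sequences with at least 50 reads, 41 were lower and 2 higher: the miR390 sequence, and AAGGGCTGAATCTCAGTGGAT (7 to 50 reads, 2.48-fold, 1.12 to 6.47), antisense to the 45S repeat at 9484 to 9504 on chromosome 2. The latter is named because so few rose by the main totals, since no sequence outside miRNA and TAS loci reached 200 reads and the rule. Without structural and organelle RNA in the totals 18 of the 54 sequences were higher and 12 lower, and relative to the median family 17 and 13. The share of 21-nt reads with a 5' A was 17.9% (17.5 to 18.3) in the input and 20.2% (19.9 to 20.4) in the co-IP. It was 32.3% (31.4 to 33.1) and 36.6% (35.3 to 37.9) without structural, organelle and miRNA reads, and 18.1% and 13.5% when miRNA reads were kept.

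Set against each other, both proteins held miR390 above input. By the main totals miR390 was the only one of 36 families measured in both comparisons that was higher in both. Without structural and organelle RNA 5 families were higher in both, miR390, miR159, miR408, miR5643 and miR8175, and miR161 and miR319 joined them relative to the median families and by the trimmed mean of M-values. By the range between the inputs none was. miR408, miR159, miR5643 and miR8175 were higher with AGO2 and neither with AGO7 by the main totals, miR172 was higher with AGO2 and lower with AGO7, and 23 families were lower in both by these totals. Families lower in both numbered 7 without structural and organelle RNA, 8 relative to the median families and 11 by the trimmed mean of M-values. The log2 ratio of miR390 was 2.19 with AGO7 and 2.02 with AGO2, a difference of 0.17 (-0.42 to 0.77) that counting error could cover. Relative to the median families the difference was 1.75, by the trimmed mean of M-values 0.91 (0.32 to 1.51), without structural and organelle RNA 3.64, and without miR159 in the totals -0.24, so its size and sign depended on the totals. In rank, miR390 was first of 37 families with AGO7 and the 13th of 64 with AGO2. These are different sets, since families too rare in the AGO7 pair, such as miR852 and miR841, could be ranked only with AGO2. Among families with at least 100 reads miR390 was first of 17 with AGO7 and 7th of 25 with AGO2.

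Among the 16 families with at least 100 reads in each comparison, those most in favour of AGO2 were miR408, with an AGO7 minus AGO2 log2 difference of -4.50 (-5.07 to -3.92), miR159 at -3.62 (-3.67 to -3.57), miR172 at -3.31 (-3.70 to -2.92), miR160 at -2.57 (-3.03 to -2.10) and miR168 at -2.22 (-2.39 to -2.05). Relative to the median families these differences were -2.92, -2.04, -1.73, -0.99 and -0.64, and without structural and organelle RNA they were -1.03, -0.16, 0.15, 0.90 and 1.24, so the direction of the last 3 flipped. Those most in favour of AGO7 were miR776 at 1.80 (1.49 to 2.11), miR845 at 1.39 (0.46 to 2.32), miR165/miR166 at 1.31 (0.94 to 1.69), miR780 at 0.82 (-0.05 to 1.68) and miR167 at 0.59 (0.41 to 0.77). All 5 of the latter were below input in both comparisons by these totals, and their differences were larger, at 3.38, 2.97, 2.89, 2.40 and 2.17, relative to the median families and, at 5.26, 4.85, 4.77, 4.28 and 4.05, without structural and organelle RNA. The largest of these differences was thus that of miR408 by the main totals and that of miR776 under both other scalings. The miR776 value rests on reads that differ from its exact mature sequence by up to 2 nt at their ends, since that sequence had 6 reads in the AGO2 pair and 1 in the AGO7 pair. The place of miR160 also depends on shifted reads, since 821 of its 1393 reads in the AGO2 pair began with A. Its guides begin with U. At the miR160b strand, which has the same mature sequence, the log2 ratio was -3.28 with AGO2 and -2.68 with AGO7. That strand alone did not favour AGO2.

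**Figure D4:**
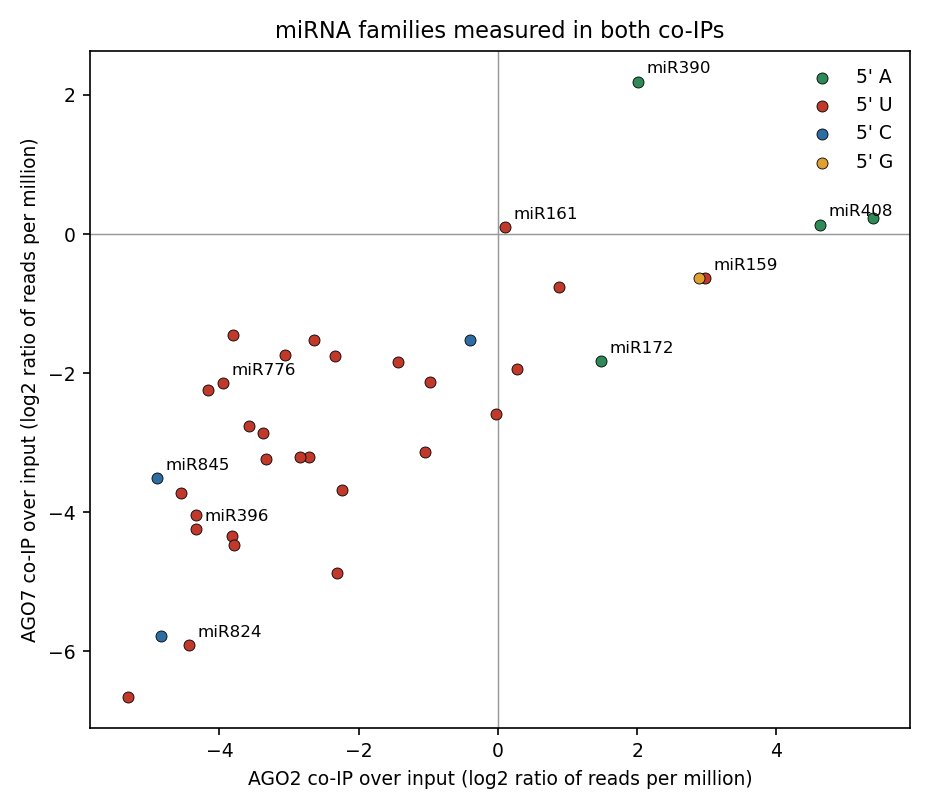
Log2 ratio of RPM, co-IP over input, for the 36 miRNA families measured in both comparisons, with AGO2 on the horizontal and AGO7 on the vertical axis and points coloured by the 5' base of the guide strand. By these totals miR390, at 2.02 and 2.19, was the only family higher by the rule on both axes, and 23 were lower on both. Without structural and organelle RNA 5 were higher on both and 7 lower on both.

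As background, the 2 inputs came from plants of different genotypes and were compared by the same rule. Of 46 measured families 6 were higher and 5 lower in the AGO7 input, and 95% of the log2 ratios lay between -2.21 and 2.06. Small RNAs of the tagged genes themselves were also counted. The AGO2 gene (AT1G31280) gave 54.5 reads of 20 to 22 nt in the AGO2 input and 1574 in the AGO2 co-IP (15.2-fold, 11.7 to 20.5), with sense reads going from 33 to 1273, and at most 1 read in either AGO7 library. The AGO7 gene (AT1G69440) gave at most 2 reads in any library.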

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

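The ratios of the TAS loci and miRNA families were planned, whereas the miR396 and miR393 star strands were singled out after their values were seen. The opposite directions of the AGO2 and AGO7 comparisons were not tested as differences with replicates, since each group had 1 library. Features that passed the rule in opposite directions with the 2 proteins were the TAS loci, with a log2 ratio of 2.33 with AGO2 and -3.19 with AGO7, and miR172, at 1.48 and -1.83. The star strand of miR396 stood at 6.67 with AGO2 and -3.17 with AGO7, and that of miR393 at 5.05 and -2.17. With structural and organelle RNA left out of the totals, miR172 lay above input with AGO7 (0.82), as did the miR393 star strand (0.48), and the miR396 star strand (-0.52) and TAS loci (-0.54) no longer passed the rule there.

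Some kinds of reads outside the measured set made up more of the co-IPs than of the inputs. Inserts too short did the opposite, at 54.4% of the AGO2 input against 7.93% of its co-IP. With AGO7 they were 75.1% of the input and 15.9% of the co-IP. Inserts of 18 to 28 nt without a perfect genome match made up 52.1% of those of the AGO2 co-IP and 46.1% of those of the AGO7 co-IP, against 22.3% and 29.1% in the inputs. Reads that began with the adaptor, and so held no insert, made up 21.5% of the AGO7 co-IP, against 0.175% of its input. No technical or biological explanation was tested for these values.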

How the results depend on the processing

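No paired analysis was possible because each group had 1 library. The scalings by the median family and without miR159, the recounts of reads shared between families, the miRNA share without structural and organelle RNA, and the range between the inputs and 4-fold for single ratios were chosen after seeing the data. Of 164 alternative values of the comparison results 130 stayed on the same side of the rule or within their interval, as did 514 of 606 for single features, of which 40 reversed, 30 no longer passed and 22 newly passed. miR390 rose with AGO7 in all of its alternatives (log2 1.80 to 4.84) and with AGO2 in all of its own (1.21 to 3.35) except beyond the range between the inputs, where 2.02 no longer passed, and the TAS loci with AGO2 in all of theirs (1.51 to 3.66). Among the settings that can move a rank, miR390 ranked first with AGO7 with the 10-nt adaptor match, exact mature sequences, both other minimums and the pseudocount of 5, and 2 against the other construct's input. Except where a setting tests fewer or more features by construction, the cause was not tested.

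Families higher with AGO7 numbered 8 without structural and organelle RNA, 7 by the trimmed mean of M-values, 8 by the median family and 2 against the other input, and families lower numbered 7, 13 and 8 under the first 3. Sequences higher with AGO7 numbered 18, 10 and 17 under those, 8 with no minimum, and 1 at 4-fold, beyond the range between the inputs, with all trimmed inserts as the total or with the higher minimum. Sequences lower with AGO7 (41 by the main setting) numbered 12, 22 and 13 under those scalings, 1947 of 101159 with no minimum, 6 with the higher minimum, 25 beyond the range between the inputs and 108 against the other input. The AGO7 TAS log2 ratio was -0.54 without structural and organelle RNA and -0.60 by the median family, no longer past the rule. The miR390 difference, AGO7 minus AGO2, excluded 0 at 1.08 with 20 to 24-nt totals, 0.91 by the trimmed mean of M-values, 0.96 against the other input, 1.75 by the median family and 3.64 without structural and organelle RNA, and turned to -0.24 without miR159.

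The higher minimum gave 8 families higher and 12 lower and 150 sequences higher with AGO2, 11 families lower with AGO7 and 5 families different between the inputs, and no minimum gave 4962 sequences higher with AGO2. Sequences lower with AGO2 (105 by the main setting) numbered 19 with the higher minimum, 4066 with none and 41 against the other input. At 4-fold the inputs differed in 6 families. The AGO2 5' A share at 21 nt was 39.8% with a 10-nt adaptor match, 84.8% without miRNA families and 92.5% with each distinct sequence counted once, and the AGO7 share 22.5% and 27.5% under the last 2.

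Log2 ratios that changed sign were, without structural and organelle RNA, AGO2 TAS3 (-0.043), miR161 (-0.71) and miR168 (-0.53), and AGO7 miR159 (2.01), miR160 (0.057), miR165/miR166 (0.91), miR167 (0.89), miR168 (0.71), miR172 (0.82), miR319 (1.89), miR393 star (0.48), miR776 (0.51) and miR8175 (2.01). By the median family they were AGO7 miR159 (1.96), miR165/miR166 (0.85), miR167 (0.84), miR168 (0.65), miR172 (0.77), miR319 (1.83), miR393 star (0.42), miR776 (0.45) and miR8175 (1.96). By the trimmed mean of M-values they were AGO7 miR159 (1.44), miR165/miR166 (0.33), miR167 (0.32), miR168 (0.13), miR172 (0.25), miR319 (1.31) and miR8175 (1.44). With 20 to 24-nt totals AGO2 miR161 (-0.62) and miR168 (-0.44) changed sign, and with all trimmed inserts AGO2 miR161 (-0.60) and miR168 (-0.42) and AGO7 miR161 (-0.30) and miR408 (-0.26). With exact mature sequences AGO2 miR161 (-2.23) did, and against the other input AGO2 miR8175 (-1.45) and AGO7 miR161 (-0.26), miR408 (-1.10) and miR8175 (3.70). Exact mature sequences of miR776 and miR8175 in both pairs, and of miR841 and miR852 in the AGO2 pair, had fewer than 10 reads and gave no value. Depth limited the AGO7 input most, where 3 reads stood for 10.7 RPM.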

Other observations

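The groups in this part, and the tests of carry-over, binding apart from the 5' A, misreading, uptake specific to AGO2 and depth, were chosen only after the result was seen. The criterion that would have spoken against binding apart from the 5' A was reworded after its result was known. Small RNAs of 20 to 22 nt from an inverted repeat, the antisense rRNA strand and protein-coding genes rose with AGO2, whereas reads of all lengths on the sense strand of protein-coding genes stood at 0.866-fold (0.854 to 0.878). The region of chromosome 3 from 1963001 to 1971000, where 84.6% of 3267 distinct sequences of 20 to 22 nt match both strands of the region as an inverted repeat does, gave 72513 co-IP reads, 9.60-fold above input (9.30 to 9.91), and 98.2% of them began with A. The gene AT3G06435 within it rose 10.1-fold (9.61 to 10.7). The antisense strand of the 45S rRNA repeat rose 11.9-fold (11.0 to 12.9), with 98.3% of co-IP reads beginning with A.

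Reads of 20 to 22 nt at protein-coding genes were higher with AGO2 for 163 of 179 measured genes, out of 27444, and lower for 0. Reads of the 532 genes of pentatricopeptide and tetratricopeptide repeat proteins, a known source of secondary siRNAs, summed to 6.78-fold above input (6.17 to 7.47). Only 14 of these genes had enough reads to be measured, and all of them rose, as did most of the 179 genes measured under the same minimum. The sequence ATTATCCCCCGTGTTTTGTCC, from the miR163 precursor (chromosome 1, 24884383 to 24884403), rose 29.7-fold with AGO2 (25.3 to 35.1), from 152 to 8587 reads, and stood at 1.65-fold with AGO7 (1.32 to 2.07), while the miR163 guide was 18.1-fold lower with AGO2.

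miR390 stood first among the families of the AGO7 co-IP. Carry-over from the AGO2 co-IP does not account for it, since at the rate of the miR396 and miR393 star strands it would give 0.187% of the miR390 reads. Whether AGO7 takes miR390 apart from its 5' A stays open, because the nearest other A family, miR5643, had 2 input and 8 co-IP reads and lay 1.96 below it (-0.13 to 4.05). miR408 and miR172 lay 2.06 (1.34 to 2.78) and 4.02 (3.43 to 4.61) below it.

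miR159b (TTTGGATTGAAGGGAGCTCTT, chromosome 1, 6220813 to 6220833) rose 45.9-fold (44.0 to 47.9) with AGO2, whereas miR159a (TTTGGATTGAAGGGAGCTCTA, chromosome 1, 27713234 to 27713254), which differs in its last base, rose 4.02-fold (3.96 to 4.08). Misreading of that base does not account for it, since 263 reads ended in U for each that ended in C. A preference of the library for inserts ending in U could not be excluded: other sequences beginning with U stood 0.46 higher in log2 when they ended in U (10 sequences) than in A (28), with a bootstrap interval of -1.89 to 2.86 that includes 0 and 1.76, the size set as the limit. The rise of miR159b relative to miR159a was larger with AGO2 than with AGO7 by 2.61 (2.46 to 2.76), which is consistent with an uptake specific to AGO2, as a hypothesis, while a preference in that library alone cannot be told apart from it.

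The AGO2 gene (chromosome 1, 11181504 to 11185396) gave small RNAs in the HA-AGO2 plants and at most 1 read in either AGO7 library. Fragments of its transcript do not account for all of the 20 to 22-nt reads, since the AGO2 input held 23 antisense and 33 sense reads (41.1% antisense, 29.2 to 54.1) and the co-IP 338 and 1273 (a lower antisense share, with an interval of 19.1% to 23.0%), but how many of the sense reads are such fragments stays open. Reads shared with other genes do not either, since 95.3% (94.2 to 96.3) of the co-IP reads matched the genome at this gene alone, nor does the depth of the AGO7 input, which would hold 21.8 reads at the level of the AGO2 input. A candidate explanation is siRNA production from the AGO2 transgene. The design does not separate it from a difference between the Col-0 and zip-1 plants, and neither was tested.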
